A study of Mus musculus with 22 samples.

How the data were processed

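The series followed gene expression in whole lungs of normal Swiss Webster mice at 11 ages, from embryonic day 12 (E12) through E14, E16 and E18, then postnatal day 1 (P1), P4, P7, P10, P14 and P21, to the adult. Per the labels, total RNA of at least 3 lungs was combined into a pool for each age, biotin-labelled cRNA was made from 10 µg of it, and every pool was hybridised once to each of the 2 oligonucleotide chips of an Affymetrix mouse set, here called chip A and chip B. The 22 arrays therefore hold 1 value per gene and age, and no age has a replicate.

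The deposited values were linear signal intensities, 1 per probe set and array, and were never negative. Per the deposited values, the authors had scaled each array as a whole, because the mean after trimming 2% lay between 500.1 and 500.2 on the chip A arrays and between 498.3 and 498.9 on the chip B arrays. How probe cells were turned into a probe set signal is not given in the sources used here. Scanner settings deposited beside the values were not used here. These trimmed means lay within the limit set beforehand, so the intensities were used as deposited, without further normalisation.

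Chip A held 6579 probe sets, of which 55 were controls, 5554 had 1 gene symbol, 197 had several and 792 had none. Some chip A controls also had a gene symbol and are counted in both classes. Chip B held 6577 probe sets, of which 55 were controls, 1986 had 1 symbol, 25 had several and 4511 had none. Symbols came from the platform annotation given with the series, and 7523 of the 7540 probe sets with 1 symbol had that symbol in the mouse gene table used. On each chip 1 probe set with missing values was left out. Signals under the chip's 25th percentile (72.3 on chip A and 47.3 on chip B) were set to that floor, so folds of genes near it depend on it and values at the floor have no order. Where most ages of an era lie at the floor, ties can also make the SE and p of a gene too small. Probe sets were kept where at least 2 of the 11 arrays lay above the chip's median signal (250.3 on chip A and 177 on chip B). Values were then taken to log2, and the probe set with the highest mean stood for each gene. That left 4130 genes, 2944 of them measured on chip A and 1186 on chip B, out of 6118 genes named on either chip. In 664 genes more than 1 probe set was kept. Probe sets of near-identical families, such as globins, ribosomal proteins and histocompatibility genes, were not separated further, and their members can share signal.

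All tests used limma 3.58.1 in R 4.3.3 on log2 values, two-sided, with Benjamini-Hochberg adjustment over the 4130 genes and a threshold of 0.05. Errors given with ± are limma's standard errors (SE) of log2 differences unless SD is written. The fits were a straight line on age order over the 11 ages, a natural spline with 3 degrees of freedom, a comparison of the 7 postnatal with the 4 embryonic ages, and a comparison of P4 to P14 (4 ages) with the 5 ages before and the 2 after, in which both differences had to pass in the same direction. With 1 pool per age, the error in every fit was the scatter of the pools around the fitted pattern. Ages of an era are not replicates of each other and neighbouring ages resemble each other, so these p-values are probably too small. The step from E18 to P1 compares 1 pool with 1 pool and has no test; genes at least 2-fold apart were counted, there and between other neighbouring ages, where the higher signal lay above the chip median, and each list's median was ranked among 10000 random lists matched on mean signal.

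Gene lists for 36 cell types, pathways and complexes were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The lists covered surfactant and type II cells, type I cells, club cells and airway secretion, ciliated cells, neuroendocrine cells and nerve, branching and patterning, homeobox genes, cell cycle, erythroid cells, elastic fibre, interstitial collagen, other matrix proteins, basement membrane, matrix proteases, endothelium, smooth muscle, macrophages, neutrophils, lymphocytes, histocompatibility classes I and II, antioxidant and xenobiotic enzymes, retinoid pathway, imprinted and IGF genes, heart and skeletal muscle, liver and yolk sac, cartilage, fat, squamous epithelium, ion and water transport, glucocorticoid response, immediate early and heat shock genes, clock, oxidative phosphorylation, ribosomal proteins, and splicing and chromatin. Each was tested with limma's camera at its preset correlation of 0.01 between genes, with adjustment over the 36 lists, and again with an estimated correlation. For P4 to P14 camera tested that phase against the mean of the ages before and after. The rule named the 10 largest rises and 10 largest falls between eras among genes that also passed the age order line with the same sign. It also named up to 4 members of each list with the largest called difference, or the largest 2 where none passed. From the step at birth it took the 6 largest rises and falls kept on both sides, and it added 24 lung genes named in any case. Of these 24, Fbn1, Sftpa1, Sftpb and Aqp5 were not on either chip by the annotation used.

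The tests were checked on simulated data built from the real gene means and the real scatter around the spline, with 200 of 4130 genes changed. Of genes changed 2-fold, 4-fold and 8-fold, the line recovered 65.7%, 88.1% and 98.5%, the spline 16.4%, 55.2% and 89.4%, the era comparison 76.1%, 95.5% and 98.5%, and the P4 to P14 comparison 47.8%, 89.6% and 97.0%. False calls among 3930 unchanged genes numbered 3, 5, 15 and 1. The simulated era and P4 to P14 changes had no trend within an era or phase, which the real courses do have. Their shares therefore do not bound those tests on the real data. Scatter was drawn independently for each age, so the false calls do not cover neighbouring ages that resemble each other. In the simulated lists camera called the raised list and 0 of 35 unchanged lists at either correlation. The simulated genes varied independently of each other, so this check does not cover lists of correlated genes. It cannot decide between the preset and the estimated correlation. The number of arrays limits the precision of every value. Alternatives covered the scaling between arrays, the floor, the filter, the choice of probe set, the variance model, the age coding, a rank test with 100000 permutations of the age order, each age left out, and other windows and divisions of the ages. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.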

Results

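Lungs of 11 ages were measured, 4 before birth and 7 after, with 1 RNA pool per age on both chips. Values for single ages therefore come from 1 pool (n = 1), and era means from n = 4 embryonic and n = 7 postnatal ages.

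The largest change between neighbouring ages came before birth, from E16 to E18. In that step 591 genes differed at least 2-fold, against 126 from E12 to E14, 256 from E14 to E16 and 301 from E18 to P1. After birth the counts were 158 from P1 to P4, 105 from P4 to P7, 134 from P7 to P10, 129 from P10 to P14, 201 from P14 to P21 and 225 from P21 to adult. Cell cycle genes took part in the step before E18: 59 of 61 were lower at E18 than at E16, with a median of -1.24 (log2). Sftpd, the gene of a surfactant protein of innate defence, went from 72.3, the floor, at E16 to 1635.9 at E18 and 5636.4 at P1. The first 3 principal components held 61.1%, 10.7% and 6.61% of the variance. The pools hybridised to both chips gave the only technical repeat: for 231 genes with a kept probe set on each chip, the median correlation across ages was 0.682 (quartiles 0.287 and 0.928), and 83.5% had the same sign between eras.

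**Figure D1:**
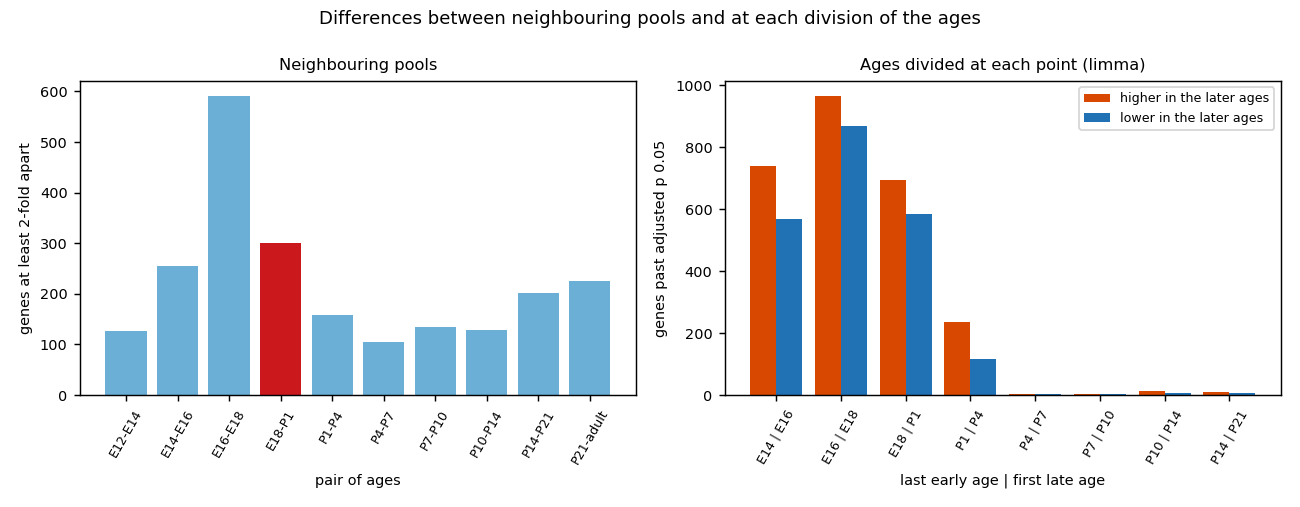
Genes at least 2-fold apart between neighbouring ages, each age being 1 pool.

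Along the order of ages 913 genes rose and 813 fell. Among the rising genes were H2-Aa, a class II antigen-presenting chain (adjusted p = 1.56e-06), Sod3, the extracellular superoxide dismutase (adjusted p = 1.53e-05), Aldh1a1, a retinaldehyde dehydrogenase (adjusted p = 4.6e-05), and Hpgd, which breaks down prostaglandins (adjusted p = 7.29e-05). Igf2, a fetal growth factor (adjusted p = 2.1e-05), Rpl13a of the large ribosomal subunit (adjusted p = 0.000111) and Cks1b, a partner of cyclin-dependent kinases (adjusted p = 0.000217), fell. A smooth change of any shape was called for 1743 genes (42.2%), 304 of which had no call on the straight line. Tnc, Eln, Col1a1, Col3a1, Col4a1 and Fn1 of the matrix lists were among these 304. Camera called 22 lists on the age order at the preset correlation and 0 with the estimated one. They were the 25 lists called between eras, described below, without basement membrane, smooth muscle, cartilage and ion and water transport, and with the clock list (4 of 6 rising, 0 falling, adjusted p = 0.0477, and adjusted p = 0.209 with an estimated correlation).

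Between eras 695 genes were higher and 586 lower after birth, 1281 of 4130 (31.0%), by at least 4-fold in 90 and 16. Here a gene that rose or fell had a higher or lower mean over the postnatal ages, wherever along the course the change took place. The largest rises were in Cd74, the class II invariant chain, by 5.23 ± 0.69 (log2 ± SE, adjusted p = 0.00121), from 7.50 ± 1.92 (SD, n = 4) to 12.73 ± 0.74 (n = 7), in Sftpd by 4.88 ± 0.71 (adjusted p = 0.00158), in Hpgd by 4.87 ± 0.48 (adjusted p = 0.0002) and in the fatty acid receptor Cd36 by 4.60 ± 0.82 (adjusted p = 0.00379). They were followed by the water channel Aqp1 (4.12 ± 0.85), the club cell oxidase Cyp2f2 (4.05 ± 0.77), the methyltransferase Inmt (3.97 ± 1.00), the glutathione transferase Gsta3 (3.93 ± 0.64), the calcium-binding S100g (3.84 ± 0.80) and the endothelial phosphatase Ptprb (3.83 ± 0.56). The largest falls were in the embryonic globin Hbb-y (-4.61 ± 1.05, adjusted p = 0.00953), the imprinted Dlk1 (-4.37 ± 1.17), the embryonic globin Hba-x (-3.05 ± 0.73), the non-coding Rab26os (-2.59 ± 0.18, adjusted p = 2.5e-05) and Cad of pyrimidine synthesis (-2.39 ± 0.59). They were followed by the mitotic kinase Melk (-2.27 ± 0.75), the imprinted Nnat (-2.22 ± 0.56), Igf2 (-2.21 ± 0.42, adjusted p = 0.00528), the fetal microfibril gene Fbn2 (-2.20 ± 0.67) and the chromatin factor Hmga2 (-2.19 ± 0.62). Every postnatal signal of Hbb-y and Rab26os, and most of those of Cad and Melk, were at the floor, as were all embryonic signals but that of E18 for Hpgd, Inmt and Gsta3. The sizes of these differences depend on the floor, which Hbb-y, Cad and Melk also reached at E18, and ties can make an SE and p too small. The counts rest on few embryonic ages: without E12 they were 379 and 213, without E14 342 and 175, without E16 the lower count was 359, and without E18 it was 883. Without E14 the calls of Inmt (adjusted p = 0.0541), Dlk1 (0.053), Hba-x (0.0501), Cad (0.0541), Melk (0.132), Fbn2 (0.0936) and Hmga2 (0.0824) were lost, as was that of Nnat without E12 (0.0549). Without E12 and P7 together, an alternative added after the data were seen, the counts were 274 and 150 and Hbb-y (adjusted p = 0.0571) was lost too.

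A step at birth beyond a straight line was called for 4 genes higher and 1 lower when age order was added to the fit, with 496 at an unadjusted p under 0.05. These 5, chosen after their values were seen, were Angptl4 (1.71 ± 0.26), Il1rn (1.47 ± 0.23), Ltb (2.10 ± 0.31), Thbs3 (2.76 ± 0.44) and Rab26os (-2.32 ± 0.32), each with adjusted p = 0.047. Tied floor values enter this too, in all postnatal ages for Rab26os and in 3 ages for Ltb. Limma on E16 and E18 against P1 and P4 alone called 0 higher and 0 lower, with 281 genes at an unadjusted p under 0.05. Dividing the ages before E18 in place of birth, an alternative added after the data were seen, called 966 higher and 868 lower, and 1180 genes were called at both points with the same sign.

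In the epithelial lists more genes were higher than lower at postnatal ages, and much of the difference arose before birth. From E16 to E18 the list medians moved by 1.14 (type II), 1.29 (type I), 1.69 (club cells) and 0.77 (ion and water transport), against -0.096, 0.21, 0.18 and 0.14 from E18 to P1. Of 15 surfactant and type II genes 8 rose, 0 fell and 7 did not pass (9 and 0 adjusted over the list alone), among them S100g, Sftpd and the phosphate carrier Slc34a2 (3.83 ± 0.92, adjusted p = 0.0118, and 0.0504 without E14); the list was called by camera at adjusted p = 0.00124, and adjusted p = 0.358 with an estimated correlation. Sftpc, the gene of surfactant protein C, was already at 1436.8 at E12 and did not pass (-0.48 ± 0.66, adjusted p = 0.611). Of 9 type I genes 7 rose and 2 did not pass (8 adjusted over the list alone, median 1.64). Camera called the list at adjusted p = 0.000195, and adjusted p = 0.257 with an estimated correlation. Risers included Sema3b (2.75 ± 0.38), the vessel growth factor Vegfa (2.45 ± 0.45), Sema3e (1.66 ± 0.21) and the receptor Ager (3.54 ± 1.00, adjusted p = 0.0211, and 0.083 without E12). Of 9 club cell and airway secretion genes 7 rose and 2 did not pass (7 adjusted over the list alone, median 2.73), with Cyp2f2, haptoglobin Hp (3.51 ± 0.77), Aldh1a1 (3.05 ± 0.62) and the oxidase Fmo1 (2.93 ± 0.64). Camera called that list at adjusted p = 0.00221, and adjusted p = 0.295 with an estimated correlation, while Scgb1a1, the main club cell secretory gene, did not pass (0.28 ± 0.29, adjusted p = 0.501). Ion and water transport had 3 risen and 6 not passed of 9 (4 adjusted over the list alone). With camera the list had adjusted p = 0.0221, and adjusted p = 0.262 with an estimated correlation. Among the risers were Aqp1, the kinase Sgk1 (3.38 ± 0.28, adjusted p = 5.4e-05) and the sodium pump subunit Atp1b3 (0.50 ± 0.12, adjusted p = 0.0119, and 0.0608 without E12 and P7).

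Other epithelial and nerve lists had few called genes. Of 7 ciliated cell genes 1 rose and 6 did not pass (1 adjusted over the list alone), the riser being the lipid transfer gene Pltp (1.18 ± 0.32, adjusted p = 0.018, and 0.0651 without E14). The median of that list was -0.14, its mean 0.08 and its camera direction down (adjusted p = 0.72). Of 8 neuroendocrine and nerve genes 1 fell and 7 did not pass (0 adjusted over the list alone), the adhesion gene Ncam1 (-0.41 ± 0.13, adjusted p = 0.0313, and 0.108 without E14). Here the median was -0.04, the mean 0.15 and the camera direction up (adjusted p = 0.919). Of 8 squamous epithelium genes 0 rose, 0 fell and 8 did not pass by limma (camera adjusted p = 0.72), among them the mucosal keratin Krt4 (1.22 ± 1.08, adjusted p = 0.414) and Krt17 (-0.52 ± 0.36, adjusted p = 0.284). The P21 pool stood out beside this list, with a Krt4 signal of 4292, against 565.1 at P10 and at most 147.8 elsewhere.

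Of 25 endothelial genes 21 rose, 0 fell and 4 did not pass (22 adjusted over the list alone, median 1.37). Examples were Ptprb, the hypoxia factor Epas1 (2.90 ± 0.40), the carbonic anhydrase Car4 (2.71 ± 0.37), the junction gene Pecam1 (1.93 ± 0.38) and the VEGF receptor Kdr (1.39 ± 0.24). Camera called endothelium at adjusted p = 1.62e-09, and adjusted p = 0.257 with an estimated correlation. Of 16 smooth muscle genes 7 rose and 9 did not pass (7 adjusted over the list alone). The camera test gave adjusted p = 0.00221, and adjusted p = 0.257 with an estimated correlation. Examples were the filament gene Des (1.38 ± 0.22) and the contractile genes Cnn1 (1.32 ± 0.31) and Tagln (1.21 ± 0.21). Of 11 fat genes 5 rose and 6 did not pass (7 adjusted over the list alone). The list as a whole had a camera adjusted p = 0.0025, and adjusted p = 0.295 with an estimated correlation. Risers included Cd36 and the lipid droplet gene Cidec (1.45 ± 0.32, adjusted p = 0.00837, and 0.136 with the floor at the 40th percentile). Of 23 heart and skeletal muscle genes 10 rose, 2 fell and 11 did not pass (11 and 2 adjusted over the list alone). Camera called the list at adjusted p = 0.00221, and adjusted p = 0.358 with an estimated correlation. Among the risers were the heart and muscle genes Cox6a2 (2.36 ± 0.46), Myl4 (1.88 ± 0.35) and Tnnt2 (1.66 ± 0.39). Acta1, skeletal muscle actin, named after its values were seen, was at 8466 in the P21 pool and at most 1516 elsewhere.

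In the immune lists genes were called higher and 0 lower at postnatal ages, again with a share of the difference before birth. From E16 to E18 the medians moved by 1.23 (neutrophils, 7 of 9 at least 2-fold), 0.83 (class II), 0.65 (class I and interferon), 0.49 (macrophages) and 0.45 (lymphocytes), and the centred neutrophil median then had no single direction, at 0.29 at E18, 0.61 at P1, 0.07 at P7, 0.64 at P14 and 0.20 in the adult. Of 24 macrophage genes 18 rose and 6 did not pass (22 adjusted over the list alone, median 1.06). With camera the list had adjusted p = 6.85e-09, and adjusted p = 0.257 with an estimated correlation. Examples were the pore-forming Mpeg1 (3.23 ± 0.59) and the lysosomal protease Ctss (2.31 ± 0.52, adjusted p = 0.00904, and 0.0528 without E12 and P7). Of 9 neutrophil genes 5 rose and 4 did not pass (6 adjusted over the list alone). The camera test gave adjusted p = 0.0025, and adjusted p = 0.311 with an estimated correlation. Risers included the iron-binding Lcn2 (2.12 ± 0.47) and the calcium-binding S100a8 (1.44 ± 0.30). Of 15 lymphocyte genes 6 rose and 9 did not pass (6 adjusted over the list alone). The list as a whole had a camera adjusted p = 0.00124, and adjusted p = 0.257 with an estimated correlation. Among the risers were the cytokine Ltb (2.45 ± 0.18, adjusted p = 2.53e-05) and the antibody chain Ighm (2.11 ± 0.23). Beside this list, the P1 pool held the highest signals of Cd3d (794.8), Cd3g (663.9), Cd8a (641.5) and Thy1 (1211), named after their values were seen. Class II presentation had 5 risen and 3 not passed of 8 (7 adjusted over the list alone, median 2.03), with Cd74, H2-Aa (2.76 ± 0.48) and H2-Ab1 (2.71 ± 0.47). Its camera values were adjusted p = 0.000217, and adjusted p = 0.295 with an estimated correlation. Class I presentation and interferon genes had 15 risen and 5 not passed of 20 (16 adjusted over the list alone, median 1.40), with the ubiquitin-like Isg15 (2.75 ± 0.31), the peptide transporter Tap2 (2.14 ± 0.44) and H2-K1 (2.03 ± 0.43). Camera called them at adjusted p = 9.72e-09, and adjusted p = 0.257 with an estimated correlation.

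**Figure D2:**
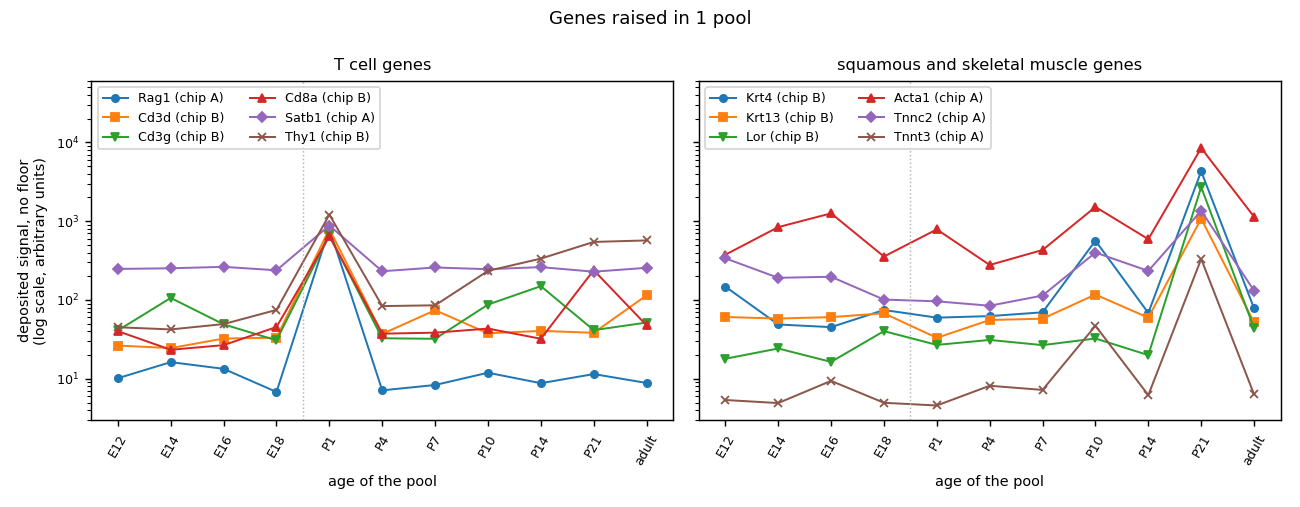
Signals of T cell, squamous and muscle genes by age, with 1 pool per age; the genes were chosen after their values were seen.

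The 4 lists of cell cycle, ribosomal proteins, splicing and chromatin, and oxidative phosphorylation had fallen genes and 0 risen. Of 61 cell cycle genes 44 fell, 0 rose and 17 did not pass (51 fallen adjusted over the list alone), with a median of -1.17 and a camera adjusted p = 5.44e-13, and adjusted p = 0.32 with an estimated correlation. Cks1b fell by 1.97 ± 0.43 (adjusted p = 0.0082) and the topoisomerase Top2a by 2.12 ± 0.66 (adjusted p = 0.0308, and 0.102 without E14). Of 38 ribosomal protein genes 26 fell, 0 rose and 12 did not pass (30 fallen and 1 risen adjusted over the list alone, median -0.65). Camera called the list at adjusted p = 5e-11, and adjusted p = 0.257 with an estimated correlation. Examples were Rpl13a (-1.96 ± 0.25), Rps26 (-1.32 ± 0.19), Rpl36 (-1.19 ± 0.17) and Rpsa (-1.11 ± 0.21). Of 43 splicing and chromatin genes 22 fell and 21 did not pass (27 adjusted over the list alone, median -0.77), with the chromatin remodeller Smarcc1 (-1.62 ± 0.31) and the spliceosome gene Snrpg (-1.50 ± 0.28); camera gave adjusted p = 9.45e-10, and adjusted p = 0.322 with an estimated correlation. Of 32 oxidative phosphorylation genes 10 fell and 22 did not pass (10 adjusted over the list alone, median -0.35), with Cox7a2 of the terminal oxidase (-0.71 ± 0.15) and Ndufv2 of complex I (-0.65 ± 0.18, adjusted p = 0.0172, and 0.0667 without E14). Camera called this list at adjusted p = 0.000112, and adjusted p = 0.31 with an estimated correlation.

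**Figure D3:**
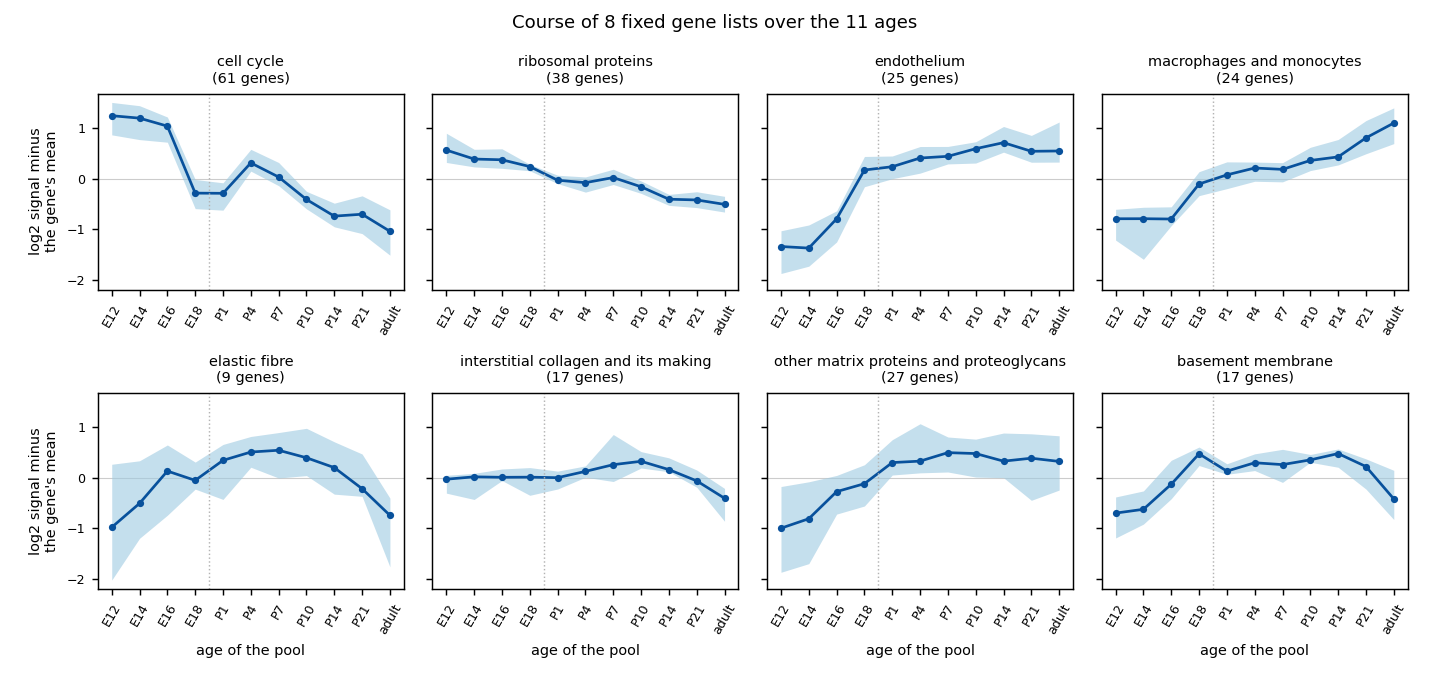
Median courses of gene lists over the 11 ages, with 1 pool per age.

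Of 20 imprinted and IGF genes 8 fell, 1 rose and 11 did not pass (8 and 1 adjusted over the list alone, median -0.998), with Igf2, the non-coding H19 (-2.04 ± 0.57, adjusted p = 0.0203, and 0.0733 without E12) and, rising, the vessel wall gene Igfbp7 (3.07 ± 0.68). Camera gave adjusted p = 0.00757, and adjusted p = 0.257 with an estimated correlation. Of 4 cartilage genes 3 fell and 1 did not pass (3 adjusted over the list alone, median -0.57, camera adjusted p = 0.0221, and adjusted p = 0.257 with an estimated correlation), led by Mia (-1.86 ± 0.30, adjusted p = 0.0027). Branching and patterning had 2 risen, 5 fallen and 23 not passed of 30 (1 and 4 adjusted over the list alone, camera adjusted p = 0.487), with the Wnt antagonist Sfrp2 (-1.93 ± 0.47, adjusted p = 0.0126, and 0.0535 without E14) and the hedgehog effector Gli2 (-1.36 ± 0.38, adjusted p = 0.0189, and 0.0748 without E12). Of 13 homeobox genes 2 fell and 11 did not pass (0 adjusted over the list alone, camera adjusted p = 0.0568), Hoxb6 (-1.08 ± 0.35, adjusted p = 0.0367, and 0.135 without E12) and Hoxb3 (-0.95 ± 0.30, adjusted p = 0.0326, and 0.101 without E12). Of 15 erythroid genes 2 fell, Hbb-y and Hba-x, and 13 did not pass (2 adjusted over the list alone); the median was 0.03, the mean -0.56 and the camera direction down (adjusted p = 0.602). Hba-x did not pass without E14 (adjusted p = 0.0501). Of 8 liver and yolk sac genes 2 fell and 6 did not pass (1 adjusted over the list alone), albumin Alb (-1.07 ± 0.37, adjusted p = 0.0458, and 0.127 without E14) and Apoa4 (-0.99 ± 0.27, adjusted p = 0.0172, and 0.0605 without E12). That list had a median of 0.06, a mean of -0.29 and a camera direction of down (adjusted p = 0.477). Of 13 retinoid genes 2 rose, 3 fell and 8 did not pass (3 and 3 adjusted over the list alone), with Aldh1a1 and Rarres2, a chemoattractant (2.91 ± 0.66, adjusted p = 0.0555 without E12 and P7), rising and the binding protein gene Crabp2 falling (-0.74 ± 0.17, adjusted p = 0.0564 without E12 and P7). Its median was 0.10, its mean 0.42 and its camera direction down (adjusted p = 0.994).

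Among genes of stress, hormone response and detoxification more rose than fell after birth. Of 25 immediate early and heat shock genes 14 rose, 5 fell and 6 did not pass (16 and 5 adjusted over the list alone, median 0.98), with the phosphatase Dusp1 (3.35 ± 0.46) and the transcription factors Fos (3.11 ± 0.62) and Klf4 (2.88 ± 0.46). The 5 that fell, named after their values were seen, were Hspe1 (-1.40), Hspd1 (-1.13), Hsph1 (-0.96), Hspa8 (-0.68) and Hsp90aa1 (-0.67), while Hspb1 (0.98, adjusted p = 0.078) and Dnajb1 (-0.15, adjusted p = 0.374) did not pass. Camera called the list at adjusted p = 0.00112, and adjusted p = 0.257 with an estimated correlation. Of 18 glucocorticoid response genes 8 rose, 2 fell and 8 did not pass (9 and 2 adjusted over the list alone). With camera the list had adjusted p = 0.00818, and adjusted p = 0.334 with an estimated correlation. Risers included Sgk1, Dusp1 and Lcn2. Of 36 antioxidant and xenobiotic genes 11 rose, 2 fell and 23 did not pass (11 and 2 adjusted over the list alone). The camera test gave adjusted p = 0.029, and adjusted p = 0.357 with an estimated correlation. Among the risers were Cyp2f2, Gsta3, Sod3 (3.41 ± 0.57) and Aldh1a1. Of 6 clock genes 1 rose and 5 did not pass (1 adjusted over the list alone, camera adjusted p = 0.22), the nuclear receptor Rora (1.37 ± 0.37, adjusted p = 0.0172, and 0.068 without E12).

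Of 9 elastic fibre genes 3 rose, 2 fell and 4 did not pass (4 and 2 adjusted over the list alone, camera adjusted p = 0.732). Ltbp2 (2.43 ± 0.51, adjusted p = 0.00766) and the cross-linking enzyme Loxl1 (2.31 ± 0.54, adjusted p = 0.01) rose. Fbn2 fell (adjusted p = 0.0283, and 0.0936 without E14). Elastin Eln (0.47 ± 0.51, adjusted p = 0.512), the cross-linking enzyme Lox (-0.83 ± 0.48, adjusted p = 0.208) and the microfibril gene Mfap2 (-0.47 ± 0.23, adjusted p = 0.129) did not pass. On the age order this list had a median slope of 0.02 per age and a camera direction of down (adjusted p = 0.667). Of 17 interstitial collagen genes 1 rose and 16 did not pass (0 adjusted over the list alone, camera adjusted p = 0.72), the collagen-binding Sparc (0.80 ± 0.25, adjusted p = 0.0316, and 0.117 without E14), while Col1a1 was at -0.24 ± 0.39 (adjusted p = 0.665) and Col3a1 at 0.19 ± 0.30 (adjusted p = 0.657). Of 27 other matrix genes 11 rose, 1 fell and 15 did not pass (12 and 1 adjusted over the list alone, median 0.85), with the growth factor modulator Ccn2 (3.62 ± 0.48), the adhesion gene Postn (2.66 ± 0.62, adjusted p = 0.0548 without E12 and P7), Thbs3 (2.61 ± 0.24) and the proteoglycan Ogn (2.31 ± 0.52); camera gave adjusted p = 0.000238, and adjusted p = 0.257 with an estimated correlation. Tenascin Tnc (1.67 ± 0.73, adjusted p = 0.099) and fibronectin Fn1 (0.85 ± 0.43, adjusted p = 0.148) did not pass. Of 17 basement membrane genes 6 rose and 11 did not pass (6 adjusted over the list alone). The list as a whole had a camera adjusted p = 0.0465, and adjusted p = 0.599 with an estimated correlation. Col4a5 rose by 1.06 ± 0.22, while Col4a1 did not pass (0.90 ± 0.36, adjusted p = 0.0739). Of 24 proteases and inhibitors 10 rose and 14 did not pass (12 adjusted over the list alone). Camera called the list at adjusted p = 0.00197, and adjusted p = 0.257 with an estimated correlation. Risers included the inhibitors Slpi (2.41 ± 0.49) and Timp2 (1.88 ± 0.30).

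Tenascin and elastin ran through a maximum between E18 and P7. Tnc went from 251.7 at E12 to 3465 at P7 and 244 in the adult (spline adjusted p = 0.000249), and Eln from 2409.4 at E12 to 11171.1 at E18 and 1828.7 in the adult (adjusted p = 0.00811). The spline also called Postn (adjusted p = 6.91e-06), Ltbp2 (adjusted p = 1.78e-05), Loxl1 (adjusted p = 2.58e-05), Col4a1 (adjusted p = 0.00033), Col1a1 (adjusted p = 0.000481), Fn1 (adjusted p = 0.00088) and Col3a1 (adjusted p = 0.00466), but not Lox (adjusted p = 0.0673). For P4 to P14 against both the ages before and after, limma called 0 genes higher and 0 lower, with 50 and 25 at an unadjusted p under 0.05, Tnc among them (unadjusted p = 0.00437). Camera used another contrast, P4 to P14 against the mean of the ages before and after, which does not ask a list to pass on both sides, and called 8 lists upward. They were elastic fibre (median 0.84, adjusted p = 0.00256, and adjusted p = 0.436 with an estimated correlation), interstitial collagen (adjusted p = 7.63e-05, adjusted p = 0.436 with an estimated correlation), other matrix proteins (adjusted p = 0.000853, adjusted p = 0.51 with an estimated correlation) and basement membrane (adjusted p = 7.92e-06, adjusted p = 0.51 with an estimated correlation). Proteases (adjusted p = 0.00097, adjusted p = 0.436 with an estimated correlation), endothelium (adjusted p = 7.63e-05, adjusted p = 0.747 with an estimated correlation), smooth muscle (adjusted p = 0.000412, adjusted p = 0.436 with an estimated correlation) and neutrophils (adjusted p = 0.00999, adjusted p = 0.745 with an estimated correlation) made up the rest. Against the later ages alone the median difference was 0.99 for elastic fibre (9 of 9 genes above), 0.51 for interstitial collagen (14 of 17), 0.49 for basement membrane (13 of 17), 0.26 for smooth muscle (13 of 16) and 0.23 for other matrix proteins (15 of 27). It was 0.13 for neutrophils (7 of 9), 0.06 for proteases (14 of 24) and -0.05 for endothelium (9 of 25), so endothelial genes as a list were not above the later ages. Col1a1, Col3a1, Sparc and Postn were measured on chip B, whose P7 array had a spiked CreX control at 18852, the highest of the postnatal ages.

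**Figure D4:**
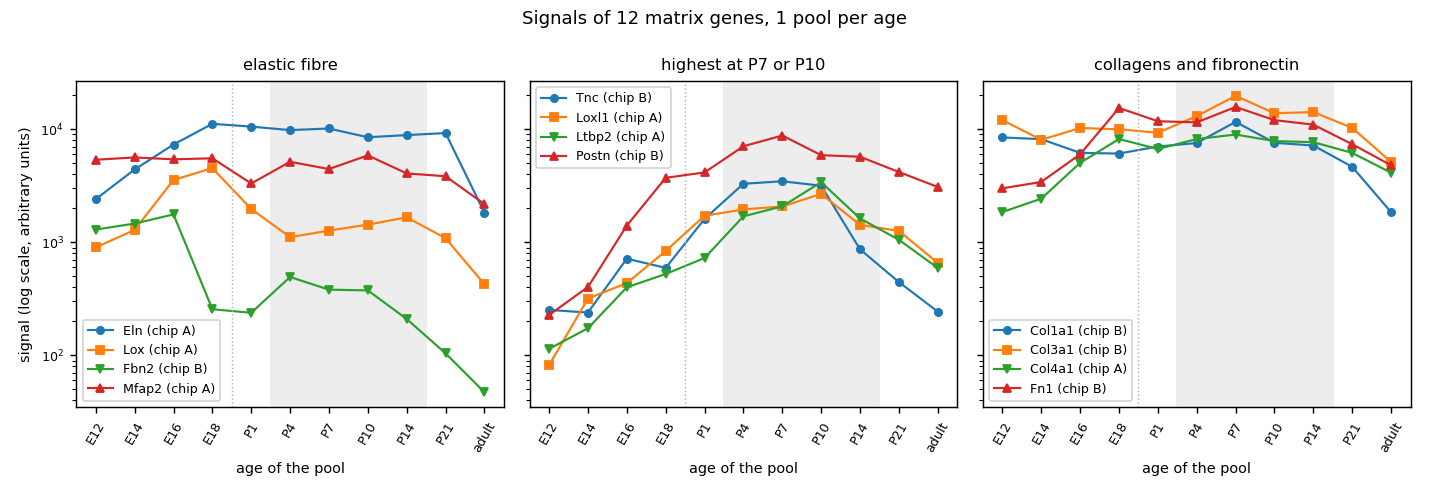
Signals of matrix genes over the 11 ages, with 1 pool per age.

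At birth, from the E18 pool to the P1 pool (n = 1 each), 170 genes were at least 2-fold higher and 131 lower with the higher signal above the chip median, and no test was made. The largest steps up that the ages on both sides kept were in the junction gene Jup (3.85), the lipid flippase Atp8a1 (3.81), the oxidase Cyp1a1 (3.45), Isg15 (3.25), the transcription factor Cebpa (2.92) and Ltb (2.56). The largest steps down were in Cnp (-2.58), Lcat of cholesterol esterification (-2.16), the muscle regulator Myog (-2.08), Rab26os (-1.89), the lipid sensor Ppara (-1.81) and G0s2, an inhibitor of lipolysis (-1.60). Against 10000 random lists matched on signal, immediate early and heat shock genes (median 0.52, 6 members counted up) and other matrix proteins (median 0.40, 9 up and 1 down) both ranked at percentile 100. Class I presentation and interferon genes ranked at 99.3, smooth muscle at 97.2, macrophages at 97.1 and endothelium at 96.9. At the low end stood ribosomal proteins (median -0.24, percentile 0.04), cartilage (-0.84, 0.46), basement membrane (-0.29, 0.94) and imprinted and IGF genes (-0.24, 2.16).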

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

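The tests of tissue admixture at P1 and P21, of an array fault and of the type II cell share were chosen only after the result was seen, while the test of saturation and the count of other divisions of the ages were set beforehand.

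Within an era, values far from the other ages were looked for in 102 sets of 4 embryonic or 7 postnatal ages, and 20 stood apart. Chance flags about 1 in 20 groups, or 5.1 of these sets, and ages with a trend are not draws from a single group. Among the embryonic ages E18 was the one apart in 9 genes. Its signal was the highest for Sftpd (1635.9), Hpgd (167.1), Inmt (1246.8), Gsta3 (127.9) and S100g (1959.2). These genes were searched because they had large era differences, and for Hpgd, Inmt and Gsta3 the earlier ages were all at the floor, which by itself sets E18 apart. It was the lowest for Melk (47.3), Igf2 (3462.2), Fbn2 (256.2) and Top2a (433.1). After birth the P4 pool stood above the other ages for Cad (109.8) and the mitotic kinase Melk (318.1), for which the floor again decides, since all other postnatal values of Cad and most of Melk were set to it, and the adult pool below them for Eln (1828.7) and Lox (426.1). On chip B spiked controls stood apart in the E12 pool, where the bacterial controls BioC (1853), BioDn (7669) and CreX (26015) had their highest embryonic signals, and in the P7 pool, where CreX (18852) did among postnatal ages. On chip A the lowest embryonic CreX signal was in the E16 pool (8933), the highest postnatal BioC signal in the P7 pool (1547), and the highest embryonic ratio of the 3′ to the 5′ actin probe set in the E18 pool (0.65). Probe sets without a gene symbol stayed out of the gene-level tests. Fitted apart, 702 of the 2707 kept (25.9%) had a smooth change with age.

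T cell genes were raised in the P1 pool. Of 15 thymocyte markers with a usable signal, 8 were highest at P1, against 5.84% of all 4130 genes, and their median lay 1.05 (log2) above that of the other ages. Usable meant above the chip median at some age, a looser filter than that of the 4130 genes. It admits genes above the median at P1 only, such as Rag1 and Cd3d, which the 4130 exclude. Part of the excess over 5.84% can therefore come from the filter. Mature T cells alone were argued against only by Rag1, which recombines antigen receptor genes in immature lymphocytes. It lay at least 11.1-fold above every other age, all of which were under the floor. A fault of an array was argued against only by the same gene. Rag1 alone was over 4-fold above its highest other age on chip A, while Cd3d and Cd3g were so on chip B. Thymus tissue in the P1 pool may account for the pattern, although Cd4 was lowest there (85.7) and Rag2 (11.3) and Ptcra (69.5) stayed under the floor. Dntt, also on the marker list, was highest at P10 by its brighter probe set and at P1 by the other. Rag2, Ptcra and Dntt were under the chip median at every age. The marker list was written after the rise had been seen, 18 of its 29 genes stand in the lymphocyte list too, and 3 of the 15 used were above the chip median at most other ages, so this stays a hypothesis, and no biological explanation was tested.

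Squamous and skeletal muscle genes were raised in the P21 pool. Of 10 squamous markers 6 were highest at P21 (60%), as were 12 of 15 skeletal muscle markers, against 12.0% of all genes. These markers also passed a looser filter than all genes did. It admits genes above the chip median at P21 only, such as Lor and Tnnt3, so part of the excess over 12.0% can come from it. Skeletal muscle alone was argued against by 3 squamous markers (Krt4, Krt13 and Lor) over 4-fold above their highest other age with P10 set aside, and a fault of an array by Lor, at least 25.9-fold up on the chip with the smaller rise, where its other ages were under the floor. Oesophagus in the P21 pool may account for both lists, in which case Krt4 at P10 (565) would mark a smaller share there. The keratins Krt1, Krt6a, Krt10 and Krt14 were not highest at P21 by their brightest probe sets, and Krt10 was lowest there (25.3, under the floor). Whether oesophagus would raise them was not tested. These lists were also written after the rise was seen and overlap the fixed lists in 14 of 22 and 16 of 21 genes, 5 of the 10 and 8 of the 15 markers used were above the chip median at most other ages, and no biological change of the lung at P21 was tested.

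Sftpc, the gene of surfactant protein C, ran an irregular course, with signals of 10931 at E16, 1654 at P7, 10058 at P21 and 630 in the adult. The P21 signal lay 2.92 (log2) above the mean of P14 and adult. For the 8 type II genes called between eras that difference had a median of -0.021 (range -0.49 to 0.61). A call between eras favours genes with little scatter among postnatal ages, so these 8 cannot decide on the share of type II cells. The centred median of all 15 genes of the list was 0.79 at P21, against 0.48 at P14 and 0.52 in the adult. Saturation stays open for the bright signals alone, since a ceiling would not lower the signals of 1654 at P7 and 630 in the adult. The test of saturation took more scatter among the 37 brightest chip A genes as the sign. It found a median scatter 0.83 times that of the next brightest group. Saturation compresses bright signals and can lower scatter, so this ratio decides nothing. With a scatter of 1.34 Sftpc was the most irregular of the 37, and a fault of this probe set could not be excluded, since no other probe set for it was kept. No biological explanation was tested.

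Chance can be excluded for the era comparison by other divisions: among 100 splits of the ages into 4 and 7, 1 split, the real one, gave as many called genes (1281), and the highest other gave 2. Most drawn splits mix early and late ages, so any trend with age separates the real split from these, and only a random grouping is excluded. The other division of the ordered ages into 7 and 4, between P7 and P10, was not drawn and called 7 genes, while the division before E18 called 1834, so birth is not singled out.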

How the results depend on the processing

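Of the named genes called between eras 0 changed direction under other scalings, floors, filters, probe set choices, variance models or ages left out. The fit with age order, E16 and E18 against P1 and P4, and other divisions of the ages were not checked for this. With quantile normalisation, however, the list medians of erythroid genes (-0.0056) and of liver and yolk sac genes (-0.05) changed sign. The fall of ribosomal proteins was smaller with quantile normalisation, with a median of -0.44 against -0.65 as deposited. Counts of the age order line, the spline and the era comparison stayed within 1.5 times of the values given under the other scalings, floors, filters, probe set choices, variance models, age codings and spline flexibilities; with quantile normalisation the era counts were 637 higher and 598 lower. The P4 to P14 comparison called 0 genes under every alternative.

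The era counts depended on the ages used. Leaving out each age in turn gave from 342 (E14) to 987 (E18) higher and from 175 (E14) to 883 (E18) lower. Fewer ages are tested there, which is no reason for the higher counts without E18. Dividing the ages before E18, so that it joined the later ages, called 966 higher and 868 lower. The cause was not tested. With age order in the fit 4 were higher and 1 lower, and E16 and E18 against P1 and P4 gave 0 and 0; the first asks for a step beyond the line and the second has 4 pools. Alternatives chosen after seeing the data left out pools. Without E12 and P7 the line called 569 rising and 509 falling, the spline 1019 and the eras 274 higher and 150 lower, and the cause was not tested. Without P1 and P21 the eras gave 554 higher, and the lower count also stayed within 1.5 times.

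The step at birth had 110 higher and 53 lower with the filter at the 70th percentile, which tests fewer genes, 412 and 467 at 1.5-fold and 55 and 29 at 3-fold, by construction of the fold. With an estimated correlation camera called 0 lists on the age order, 0 between eras and 0 at P4 to P14; the cause was not tested. Of 140 named genes 123 were called between eras. Other scalings, floors, filters, probe set choices, variance models and pairs of pools left out cost 56 of these the call. Of the 56, 54 lost it without E12 and P7 and 22 without P1 and P21. When some age was left out 49 lost it. E16 and E18 against P1 and P4, which called 0 genes, age order in the fit and the division before E18 were not counted here. Signal near the floor limits folds, and 2680 genes lay above the chip median at every age.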

Other observations

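The tests in this part were chosen only after the result was seen.

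Cell cycle genes did not fall steadily. Between the P1 and P4 pools 60 of 61 were higher at P4, with a median of 0.63 (log2), against 0.02 for all genes. Scaling of the arrays alone predicted a median under 0.25 with quantile normalisation. It was 0.58, with 59 genes higher, which argues against that scaling. The pattern rests on 1 pool per age and no biological explanation was tested.

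The adult chip B array had a 3′ actin signal of 75. The highest signals among chip B arrays were 35736 at E12, 22693 at E14 and 22077 at P7, while on chip A they lay between 11159 and 14285.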
